A study of Mus musculus with 3 samples.

How the data were processed

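RNA sequencing of platelets purified from blood of Nxf1 wild-type male BALB/c mice, 20 weeks old, was analysed in 3 libraries of 1 group. Per the labels' protocols, RNA was isolated with a Norgen kit and libraries were made with the Illumina TruSeq RNA version 2 chemistry. The deposited tables, 1 per library, give raw counts of reads per Entrez gene and a gene length. Per the submitters' processing notes, the tools named were CASAVA 1.8.2, Subread, featureCounts and edgeR 3.11.5, with mouse build mm10. Those notes give no order or settings: the annotation, the treatment of reads that map to several places and the strand setting are not given in the sources used here. Reads from near-identical copies such as globin genes, ribosomal protein genes, Tmsb4x and Ctla2a with Ctla2b can therefore be lost or divided, and their levels are stated as uncertain.

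The 3 tables list the same 9822 genes. They had been filtered before deposit by a rule not given in the sources used here: every gene had counts, and the lowest gene reached 0.238 CPM in its best library. Detection is thus compared among genes that had passed that filter. Entrez numbers were paired with symbols through the RefSeq gene table for GRCm38.p6 (9636 genes) and GENCODE M21 (2 more); 184 genes, with 0.995% of counts, had no symbol and were kept by number. Of the genes, 9107 were protein-coding, 232 long non-coding and 246 pseudogenes, the last with 1.24% of counts. Coordinates are from the RefSeq table for GRCm38, the assembly of mm10. Total counts were 26974129, 25189231 and 26111636 for replicates 1, 2 and 3, the median count per gene 96, 88 and 120, and the CPM of 3 counts, the upper limit that a count of 0 allows, 0.111, 0.119 and 0.115. Shares of counts of a single library carry exact Clopper-Pearson 95% intervals, which cover counting error only.

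Groups came from the genotype label and replicates were numbered 1 to 3; per the labels each is a batch of its own, with the same numbers, so no batch term could be fitted. The tests, the alternatives, the 31 gene lists with their 762 symbols and the rule for named genes were chosen before the data were examined. Of the symbols, 582 were in the tables, 6 were matched by an older symbol and 1 had no identifier. The rule named the 20 genes with the highest mean CPM, the 3 highest of each list, the 10 genes with the smallest p in the test of spread where the adjusted p was under 0.05, Nxf1, Nxt1, the thrombin receptors and the genes of 16 fixed pairs, and for closing observations the 10 highest genes outside all lists. A few genes that the rule names are not reported here. Every list member in the tables had counts in at least 1 library.

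CPM values are counts scaled to a library total of 1000000, using the plain total of counts assigned to genes. A gene was detected at 1 CPM or more in all 3 libraries, and each list was compared with all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 31 lists. For the spread between libraries, edgeR 4.0.16 (with limma 3.58.1 in R 4.3.3) fitted an intercept with TMM scaling to the 8289 genes with a mean of 1 CPM or more. Each gene's quasi-likelihood dispersion, with 2 residual degrees of freedom, was set against the trend by the upper tail of the F distribution, with Benjamini-Hochberg adjustment. TMM factors were 0.949, 0.955 and 1.10. Shifts of lists used log2 CPM with a prior count of 2 and 10000 random lists from 20 bins of expression, for lists with at least 3 genes tested; these describe 3 libraries and carry no p-value. Ratios of paired genes used the same prior count, and 15 of 16 pairs could be computed. Libraries were compared in pairs by a chi-square test of counts. Other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9.

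The methods were tested on simulated data. With 200 of 8289 genes changed in 1 library, 50 per fold, the spread test found 1 of 50 at 2-fold, 25 of 50 at 4-fold, 49 of 50 at 8-fold and 50 of 50 at 16-fold, with 0 false calls among 8089 unchanged genes, and 0 calls with no gene changed. Every simulated gene had its dispersion on the trend, whereas real genes scatter about it. False calls and recovery in the real data can therefore differ from these. Of 500 random lists of 30 genes among the 9822 genes, 4.4% had p under 0.05 by Fisher's exact test. A list of 30 genes with every member detected had p under 0.05, and all such lists give the same p, so this is 1 result. Of 200 lists of 20 genes drawn at random, 1% lay outside the random range with no shift, 54.5% at a log2 shift of 0.1 and 100% at 0.5.

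Alternatives were detection minimums of 0.5 and 5 CPM, 1 RPKM (CPM per 1000 bases of gene length), detection by the mean, TMM-scaled CPM, totals without the 10 highest genes, counts divided by gene length, DESeq2 1.42.0 size factors or plain totals, no filter or one of 5 CPM, a robust prior, DESeq2's dispersion outliers, removal of red cell and leukocyte genes, unmatched random lists, means for medians, a prior count of 0.5, the 10 highest genes of each library, and leaving out each replicate. Added after seeing the data were a background of all 21900 RefSeq protein-coding genes, list medians among random lists, totals without mitochondrial genes, red cell shares without globins, leukocyte shares without Lyz2, and shifts and CPM of named genes under other settings. No groups were compared, since the 3 libraries form 1 group, and no deposited column of sample values was left out. For the closing observations, further lists of red cell genes (30 symbols, 21 in the tables, 17 tested) and B cell genes (28 symbols, 28 in the tables, 25 tested) were fixed after the first shifts had been seen. For 70 ribosomal protein genes, 50-base stretches of GENCODE M21 transcripts were compared with those of all other genes, with 100000 permutations. Sequencing reads were not analysed here.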

Results

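Messenger RNA was profiled in platelets, the small anucleate blood cells shed by megakaryocytes, purified from the blood of male BALB/c mice aged 20 weeks and wild type for Nxf1, the main receptor for export of mRNA from the nucleus. There were 3 libraries in 1 group, replicates 1 to 3. The labels assign each replicate a batch of its own, so the animal and the batch cannot be told apart. The design calls the samples independent without saying that each came from a separate mouse, so errors, and the p-values of the edgeR test of spread, measure the spread between these samples, which may be technical. The p-values of gene lists are over genes, which are not independent replicates. The tables held 26974129, 25189231 and 26111636 counts for replicates 1, 2 and 3 over the same 9822 genes. With 1 group, the data can answer which RNAs these platelet preparations held and at what level, and where the 3 libraries differed. Since genes of red cells and B cells were also found, an RNA at a few CPM cannot be assigned to platelets alone. All pairs of libraries differed beyond sampling noise, with a chi-square per degree of freedom of 122.5 (1 against 2), 117.7 (1 against 3) and 20.8 (2 against 3), so no pair was 1 table given under a pair of names; at this depth the test does not show that samples were separate. The larger values rested on the 22 genes that varied most between libraries, described further on. Without them they were 10.2, 13.3 and 20.0. Across 8289 genes, which are not independent replicates, Pearson's r of log2 CPM (counts scaled to a library total of 1000000) was 0.991 (1 and 2), 0.987 (1 and 3) and 0.989 (2 and 3), and Spearman's rho 0.983, 0.974 and 0.977. These measures ranked the pairs differently.

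Nxf1 itself (Entrez gene 53319, chromosome 19, 8757103 to 8770910 in GRCm38) was present at 3.04, 2.94 and 5.86 CPM in replicates 1, 2 and 3, from 82, 74 and 153 counts. Its partner Nxt1, which forms the export heterodimer with it, was at 1.22 ± 0.397 CPM (SD, n = 3), from 22, 31 and 42 counts. In the mRNA export list 28 genes were under 10 CPM. Of its 38 genes 33 were in the tables and 30 passed 1 CPM in all 3 libraries, a share not distinguishable from that of other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.256). The median member was at 3.39 CPM and the list took 0.0316% of counts. Its 3 highest genes were Cetn2 at 154 ± 4.10 CPM (SD, n = 3), Zc3h11a at 18.2 ± 3.46 CPM and Poldip3 at 16.9 ± 1.08 CPM.

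A few RNAs made up much of the profile. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 came first, at 153422 ± 10544 and 81982 ± 3206 CPM (SD, n = 3), together 23.5% ± 1.37 of counts. Next were Ctla2a (chromosome 13, 60934155 to 60936625) at 53905 ± 1214 CPM, Fth1, the ferritin heavy chain, at 34148 ± 1941 CPM, and Nrgn, a calmodulin-binding protein first known from neurons, at 31117 ± 929 CPM. Tsc22d1 followed at 24519 ± 1452 CPM, the G protein subunit gene Gng11 at 20122 ± 823 CPM and 1810058I24Rik at 12542 ± 681 CPM. The platelet chemokine genes Ppbp and Pf4, neighbours on chromosome 5 (90768518 to 90770063 and 90772435 to 90773383), were at 10169 ± 536 and 10002 ± 331 CPM. These 10 genes held 41.6% of counts in replicate 1 (95% Clopper-Pearson interval 41.57% to 41.60%), 45.2% in replicate 2 (45.15% to 45.19%) and 42.8% in replicate 3 (42.80% to 42.84%). Such intervals cover counting error only. The 100 highest genes held 68.7% ± 1.21 of counts and the 1000 highest 92.8% ± 0.645 (SD, n = 3).

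The rest of the 20 highest genes fell into several classes. Cd9, a tetraspanin of the platelet surface, was at 9583 ± 500 CPM, Itga2b, the integrin alpha IIb chain, at 7456 ± 589 CPM, and Myl9, a myosin light chain, at 6343 ± 456 CPM (SD, n = 3). The mitochondrial gene mt-Co1 was at 6060 ± 579 CPM and B2m, the light chain of class I histocompatibility molecules, at 5192 ± 136 CPM. Ctla2b was at 5044 ± 192 CPM, the integrin-linked kinase partner Parvb at 5010 ± 554 CPM and the calcium pump Atp2a3 at 4592 ± 180 CPM. The globin genes Hba-a1 and Hbb-b1 were among the 20 only through their level in replicate 1: Hba-a1 was at 20678, 2768 and 3424 CPM and Hbb-b1 at 14451, 1104 and 1551 CPM in replicates 1, 2 and 3. Ctla2a and Ctla2b, and the globin genes, are close copies whose reads the counting could have divided between them, so the level of each alone is uncertain.

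**Figure D1:**
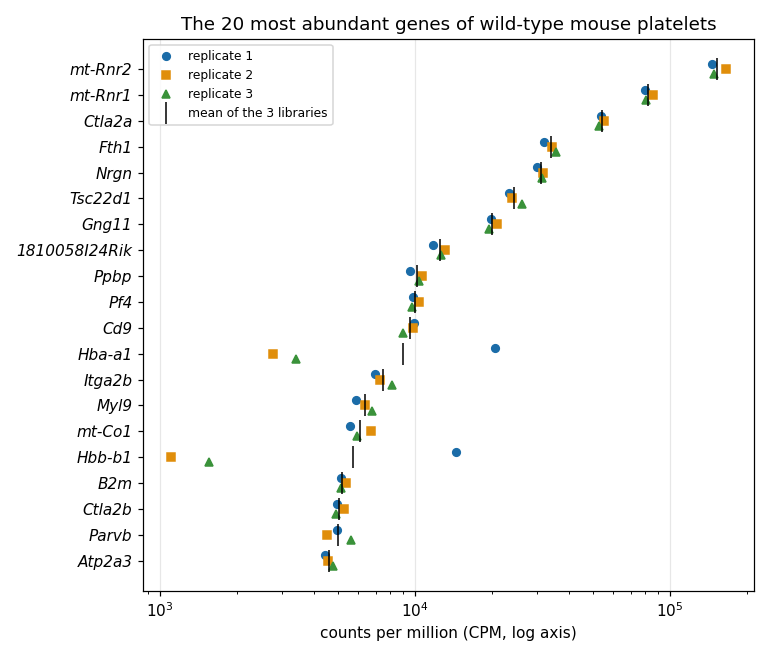
The 20 genes with the highest mean level in purified platelets, in CPM on a log axis; points are the 3 libraries and the bar marks their mean. The 3 points of most genes nearly coincide, while Hba-a1 and Hbb-b1 stand apart in replicate 1, at 20678 and 14451 CPM.

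In all, 7633 genes reached 1 CPM in every library. Among 31 gene lists, 7 were detected more often than the other genes of the tables and 1 less often (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p under 0.05). All 40 cytoskeleton genes (adjusted p = 0.00213), all 37 activation signalling genes (0.00262), all 31 translation factors (0.00562) and 66 of 70 ribosomal protein genes (0.00262) were detected, against 77.6% of genes outside the signalling list. All 22 adhesion receptor genes (0.0402), 27 of 28 genes of granule biogenesis and release (0.0478) and all 20 megakaryocyte transcription factors (0.0478) were also detected more often. The natural killer cell list lay below, with 2 of 7 genes detected (0.0402). The granule biogenesis and transcription factor calls were lost whichever replicate was left out, at adjusted p values of 0.0736 to 0.129 and 0.0544 to 0.110. At 5 CPM the granule biogenesis (0.0536) and natural killer cell (0.111) calls were lost, and the latter also at 1 RPKM (CPM per 1000 bases of gene length; 0.444) and against all RefSeq protein-coding genes, a background chosen after seeing the data (0.446). The adhesion receptor call was lost without replicate 1 (0.0832) or 2 (0.0695) and the natural killer cell call without replicate 1 (0.129); 0 lists were called at a minimum of 0.5 CPM (1 at an unadjusted p under 0.05), where 9137 genes counted as detected.

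Adhesion receptor RNAs were abundant and agonist receptor RNAs mostly were not. The median of the 22 adhesion receptor genes was 856 CPM and together they took 3.44% ± 0.0753 of counts (SD, n = 3), with Clec1b, the receptor for podoplanin, at 2671 ± 73.2 CPM behind Cd9 and Itga2b. Itga2b gave 4.83 times the reads of its partner chain Itgb3 (1545 ± 141 CPM), a log2 ratio of 2.27 ± 0.13 (SD, n = 3). Scaled to gene length, it was 8.12 times. Itgb3 gave 1.54 times the reads of Itgb1 (1006 ± 97.9 CPM), a log2 ratio of 0.62 ± 0.03, but only 1.12 times on the length scale (0.16). Gp1ba (613 ± 67.8 CPM) lay below Gp1bb (827 ± 74.6 CPM), 2 chains of the receptor for von Willebrand factor, at a log2 ratio of -0.43 ± 0.07, or -0.82 on the length scale. The agonist receptor list was more uneven, with 10 of 13 genes detected and a median of 9.81 CPM. P2ry12, the ADP receptor that clopidogrel blocks, was highest at 3389 ± 133 CPM, and the ATP-gated channel P2rx1 was at 618 ± 26.1 CPM. The other ADP receptor, P2ry1, was at 79.2 ± 4.65 CPM, so that P2ry12 gave 42.7 times its reads (log2 ratio 5.42 ± 0.13), or 71.0 times on the length scale.

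The thrombin receptor genes spanned a wide range. F2rl2, which encodes the PAR3 cofactor, was at 163 ± 9.03 CPM (SD, n = 3), F2r at 9.81 ± 0.111 CPM, and F2rl3, which encodes the signalling receptor PAR4, at 2.12 ± 0.329 CPM, from 50, 51 and 65 counts. F2rl2 gave 16.5 times the reads of F2r (log2 ratio 4.04 ± 0.09) and 74.6 times those of F2rl3 (log2 ratio of F2rl3 to F2rl2 -6.22 ± 0.14), the same order in all 3 libraries. F2rl1 was not among the genes of the tables used here. These ratios are of reads, not molecules: scaled to gene length, the log2 ratio of F2rl3 to F2rl2 was -5.74. Ratios are given with their SD and without a test; an exact two-sided sign-flip test over 3 libraries cannot go below p = 0.25.

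Alpha granule cargo genes took 3.47% ± 0.126 of counts (SD, n = 3), with 22 of 24 genes detected (Fisher's exact test, adjusted p = 0.344) and a median of 120 CPM. Pf4 and Ppbp did not differ beyond the spread between libraries (log2 ratio -0.02 ± 0.06), but Pf4 was higher once reads were divided by gene length (0.85). The next cargo gene was Clu, a secreted chaperone, at 3952 ± 422 CPM. Among genes of granule biogenesis and release, the membrane fusion genes Snap23 and Stx11 were at 3504 ± 96.4 and 1156 ± 70.0 CPM and the serotonin transporter Slc6a4 at 837 ± 55.0 CPM; the list had a median of 13.9 CPM. Vamp8 (12 CPM) lay below Vamp3 (30.7 CPM) by reads, at a log2 ratio of -1.35 ± 0.11. On the length scale the pair did not differ beyond the spread between libraries (0.08 ± 0.11). For eicosanoid synthesis 7 of 10 genes were detected, led by Alox12, the platelet lipoxygenase, at 2737 ± 87.1 CPM, Alox5ap at 518 ± 25.3 CPM and the thromboxane synthase Tbxas1 at 284 ± 19.5 CPM. Ptgs1, the cyclooxygenase that aspirin blocks in platelets, was at 182 ± 20.5 CPM, and Ptgs2 was not among the genes of the tables used here.

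Signalling and cytoskeletal RNAs were carried as nearly complete sets. The activation signalling genes had a median of 85.3 CPM and took 1.49% of counts, led by the stimulatory G protein gene Gnas at 3645 ± 106 CPM, talin (Tln1), which activates integrins, at 2058 ± 167 CPM, and Rasgrp2, the exchange factor for Rap1, at 2042 ± 25.5 CPM (SD, n = 3). The cytoskeleton genes had a median of 244 CPM and took 2.87% ± 0.133 of counts. After Myl9 came the focal adhesion gene Zyx at 3913 ± 276 CPM and Tagln2 at 2060 ± 87.6 CPM. Tubb1, the beta tubulin of the platelet marginal band, gave 154 times the reads of Tubb5 (1752 ± 157 against 11.5 CPM, log2 ratio 7.27 ± 0.26), or 290 times on the length scale. Actb gave 1.98 times the reads of Actg1 (722 ± 126 against 373 ± 114 CPM, log2 ratio 0.98 ± 0.19). The megakaryocyte transcription factors, with a median of 13.9 CPM, were led by Nfe2 at 457 ± 26.8 CPM, Tal1 at 253 ± 11.1 CPM and Gata1 at 165 ± 30.3 CPM.

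In the apoptosis and lifespan list 17 of 20 genes were detected, with a median of 11.5 CPM. Stk24 was at 241 ± 4.71 CPM, Bcl2l1, which encodes the survival protein BCL-XL, at 224 ± 14 CPM, and Bid at 203 ± 5.48 CPM (SD, n = 3). Bcl2l1 gave 12.2 times the reads of Bak1, the death effector it restrains (log2 ratio 3.61 ± 0.21), 12 times those of Mcl1 (3.59 ± 0.29) and 35.7 times those of Bcl2 (5.16 ± 0.30). On the length scale these ratios were 10.3, 17.7 and 117 times. Of the 15 pairs computed, 10 had a ratio above 0 on the log2 scale in all 3 libraries. Nxf1 gave 3.05 times the reads of Nxt1 (1.61 ± 0.35, or 0.56 on the length scale), and the adaptor Alyref lay below Nxf1 (-1.30 ± 0.14, or -0.29 on the length scale).

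The translation machinery had higher median levels than nearly all random lists of the same size. By CPM, translation factors were at percentile 100 and ribosomal protein genes at percentile 99.9, a comparison added after seeing the data. Translation factors had a median of 30.7 CPM and took 0.505% of counts, led by Eif1 at 1085 ± 40.1 CPM, the poly(A)-binding protein gene Pabpc1 at 974 ± 35.4 CPM and Eef1a1 at 564 ± 95.9 CPM (SD, n = 3). Ribosomal protein genes, at a median of 9.24 CPM, took only 0.179% ± 0.0228 of counts, with Rpl41 at 367 ± 18.7 CPM, Rpl8 at 128 ± 28.8 CPM and Rpl4 at 113 ± 21.5 CPM highest. Many of these genes have near-identical copies elsewhere in the genome, so their levels are uncertain. All 15 mitochondrially encoded genes were detected (Fisher's exact test, adjusted p = 0.107) and took 25.9% ± 1.56 of counts. Nuclear genes of oxidative phosphorylation took 0.231%, with 42 of 47 detected (adjusted p = 0.168) and Cox5a at 493 ± 16.9 CPM, Cox6b1 at 270.2 ± 13.1 CPM and Ndufa4 at 256 ± 18.8 CPM leading. Glycolysis genes had 13 of 14 detected and took 0.402% of counts, led by the glucose transporter Slc2a3 at 2064 ± 14.6 CPM, Pkm at 725 ± 40.9 CPM and Hk1 at 502 ± 56.2 CPM.

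Neither the innate immunity and antigen presentation list nor any cell state list was called as detected more or less often than other genes. Their medians ran from 1.78 CPM (innate immunity and antigen presentation) to 22.7 CPM (nuclear long non-coding RNAs). In the innate immunity and antigen presentation list 7 of 12 genes were detected (Fisher's exact test, adjusted p = 0.344) and the median was 1.78 CPM. B2m and the class I genes H2-D1 (865 ± 37.8 CPM) and H2-K1 (816 ± 43.1 CPM; SD, n = 3) led it. Among interferon-stimulated genes 17 of 22 were detected, with Ifit2 at 363 ± 11.2 CPM and Ifitm3 at 78.6 ± 8.53 CPM. Immediate early and stress genes had 12 of 18 detected at a median of 2.66 CPM, with Hspa8 at 81.8 ± 8.30 CPM, Klf6 at 13.5 ± 2.06 CPM and Jund at 12.4 ± 4.06 CPM highest. Cell cycle genes took 0.00216% of counts, with 6 of 9 detected and none above Pcna at 3.82 CPM, Mcm3 at 3.58 CPM and Mcm5 at 3.53 CPM. The list fixed as nuclear long non-coding RNAs had 4 of 4 detected, with Norad, which is known as mainly cytoplasmic, at 134 ± 19.1 CPM, Tug1 at 23.6 CPM and Neat1 at 21.8 CPM.

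Markers of other blood cells were scarce apart from those of red cells. The 7 leukocyte lists together took 0.188% ± 0.0160 of counts (SD, n = 3), of which the single gene Lyz2, lysozyme, at 1387 ± 117 CPM, made up most; without it they took 0.0497%. The next monocyte and macrophage genes were Mpeg1 at 7.71 CPM and Ctss at 6.35 CPM, and 8 of 11 genes of that list were detected. All other leukocyte lists were led by genes under 130 CPM: Cd74, H2-Aa and H2-Eb1 for B cells (127 ± 35.4, 95.6 ± 27.6 and 34.9 ± 9.30 CPM; 17 of 18 genes detected), and Tcf7, Lck and Cd28 for T cells (16 ± 3.60, 12.2 and 3.93 CPM; 9 of 14). Neutrophil genes were led by S100a9, S100a8 and Retnlg (8.68 ± 3.10, 3.94 and 2.85 CPM; 5 of 6 detected). Plasma cell genes were led by Mzb1, Xbp1 and Irf4 (8.75, 3.63 and 1.66 CPM; 3 of 4 detected) and natural killer cell genes by Nkg7, Eomes and Ncr1 (4.02, 1.45 and 1.17 CPM). Of the basophil, mast cell and eosinophil list only Siglecf (2.21 CPM) and Ccr3 (0.727 CPM) were in the tables, and 1 was detected.

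The red cell list took 5.09% of counts in replicate 1 (95% Clopper-Pearson interval 5.08% to 5.10%), 0.691% in replicate 2 (0.687% to 0.694%) and 0.855% in replicate 3 (0.851% to 0.858%), a mean of 2.21% ± 2.49 (SD, n = 3) that was 0.773% without replicate 1. The 4 globin genes made up 4.81%, 0.518% and 0.673%, with Hba-a2 at 3298 ± 3949 CPM behind Hba-a1 and Hbb-b1. Of this list 15 of 19 genes were detected, 78.9% against 77.7% of other genes. By comparison, the 11 lists of platelet function held a steady share, 13.5%, 13.8% and 14.2% in replicates 1, 2 and 3. Outside the blood, 5 of 8 endothelial genes were detected, with the water channel Aqp1 at 364 ± 24.6 CPM, Tie1 at 54.7 ± 3.73 CPM and Plvap at 29.2 ± 0.600 CPM. In the organ-restricted list Mbp was at 295 ± 9.03 CPM and Syn1 at 8.03 CPM, the 2 of its 20 genes in the tables, both detected. From the hepatocyte list Trf was at 1.97 CPM, with 1 of 2 genes detected, while Alb was at 0, 5.0 and 0.536 CPM, where 0 counts in replicate 1 allow up to 0.111 CPM.

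**Figure D2:**
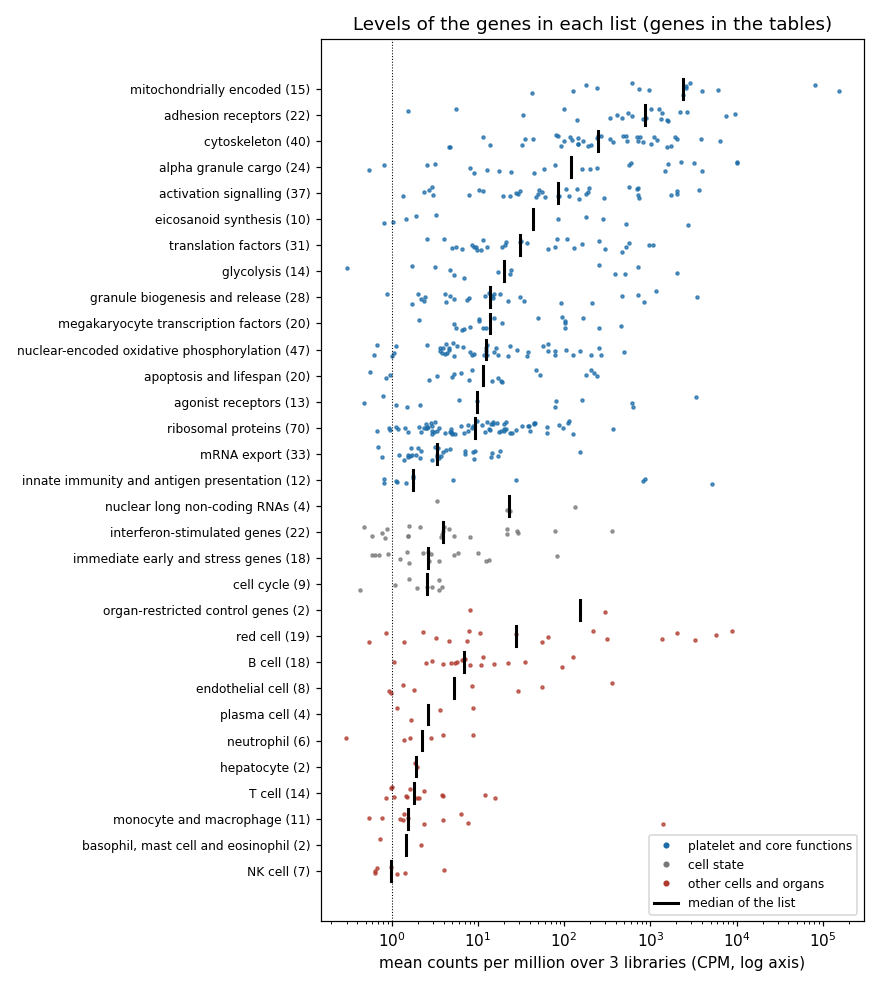
Levels of the 31 gene lists in platelets, in CPM on a log axis; each point is the mean of 1 gene over the 3 libraries and the bar marks the median of its list. Mitochondrially encoded, adhesion receptor and cytoskeleton genes have the highest medians among the platelet lists, at 2391, 856 and 244 CPM. Leukocyte lists have lower medians, the B cell list the highest of them at 6.97 CPM, and Lyz2 is their most abundant gene.

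The 3 libraries differed most in red cell genes. Of 8289 genes tested, 22 varied more between libraries than genes of the same level (edgeR's quasi-likelihood fit, Benjamini-Hochberg adjusted p under 0.05), and 21 of these were highest in replicate 1. They included 11 of the 17 red cell genes tested (13 adjusted over the list alone), an overlap beyond chance for genes drawn at random (Fisher's exact test, two-sided, p = 2.74e-26). In these 21 genes replicate 1 exceeded the mean of the others by 2.11 to 14.3 times, with a median of 7.26 times. Alas2, the first enzyme of haem synthesis in red cell precursors, was at 597, 29.2 and 54.0 TMM-scaled CPM in replicates 1, 2 and 3 (14.3 times, adjusted p = 2.37e-07). Bpgm, which makes 2,3-bisphosphoglycerate in red cells, was at 167, 12.4 and 21.9 (9.72 times, 1.05e-06). Hbb-bs (10.9 times), Hbb-b1 (11.9 times), Ube2l6 (7.65 times) and Fam220a (8.87 times) shared an adjusted p of 2.24e-06. Cdr2 (13.9 times, 4.2e-06), the mitochondrial carrier gene Slc25a39 (6.69 times, 4.94e-06), Hba-a2 (8.40 times, 4.94e-06) and the ferrochelatase gene Fech (5.52 times, 1.64e-05) completed the 10 genes with the smallest p. Alb alone was highest in replicate 2 (adjusted p = 1.38e-04).

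Without replicate 1 the edgeR test called 2 genes, Alb and Dcn, and 1 of these, Alb, was among the 22. With plain library totals 11 genes were called, all among the 22; a robust prior called 43 and DESeq2 marked 49 genes as dispersion outliers, and each set held all 22.

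Most other genes varied little. The biological coefficient of variation was 0.151, and the median coefficient of variation of CPM was 14.4% over genes at 1 CPM or more and 5.28% over the 781 genes at 100 CPM or more. Of the 22 adhesion receptor, 67 ribosomal protein and 15 mitochondrially encoded genes tested, 0 varied beyond the trend by edgeR's quasi-likelihood fit, 0 at an unadjusted p under 0.05, and 0 by DESeq2. In the mRNA export list the counts were 0, 1 and 0 of 31 genes. The alpha granule and activation signalling lists had 0 calls over all genes tested, with 2 and 3 genes at an unadjusted p under 0.05 and 1 DESeq2 outlier each. Adjusted over the list alone, 1 passed in each, Timp3 (21.1, 22.2 and 10.3 TMM-scaled CPM) and Ptpn6 (19.6, 25.5 and 40.5); both were named after their values were seen. The called interferon-stimulated gene was Rsad2.

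Whole lists also moved together in single libraries. Each gene was centred on its mean over the 3 libraries, and the median of a list was set against random lists matched on expression. Of 84 pairs of list and library 15 lay outside the central 99% of random lists, where 0.84 would for lists of genes drawn at random. These 15 came from 7 of 28 lists. Genes of 1 list can vary together and the 3 shifts of a list are linked, so the excess over 0.84 is not a test. The red cell list was higher in replicate 1 by a median log2 shift of 1.91, with all 17 genes above their means, and lower in replicates 2 (-1.03) and 3 (-0.62). The B cell list was higher in replicate 3 by 0.42, with all 18 genes above their means, and lower in replicates 1 (-0.25) and 2 (-0.20). Its share of counts was 0.0308%, 0.0305% and 0.0505%; of its genes 0 passed the edgeR test of spread over all genes, 9 had an unadjusted p under 0.05, 4 passed adjusted over the list alone, and DESeq2 marked 1. Low genes as a whole were higher in replicate 3: the median shift was 0.11 for genes at 1 to 10 CPM and -0.12 for genes at 100 CPM or more (0.25 and 0.02 with plain library totals). In that library the T cell list lay inside the random range, at 0.21 against 0.11 for the median random list (12 of 12 genes above their means; percentile 85.8), with 0.00438%, 0.00429% and 0.00659% of counts in replicates 1, 2 and 3. So did the cell cycle list, at 0.22 against 0.14 (7 of 8; percentile 76.5). Because shifts of 1 gene sum to 0, a gene above its mean in 1 library is below it in at least 1 other. The shifts of a list are therefore linked between libraries. Without replicate 1 the red cell shifts of replicates 2 and 3 became -0.14 and 0.14, and without replicate 3 the B cell shifts of replicates 1 and 2 became -0.04 and 0.04.

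Smaller shifts appeared in 5 lists. Mitochondrially encoded genes were higher in replicate 2 by 0.19, with all 15 genes above their means, and in replicate 1 lay at -0.04 against 0.05 for the median random list. Ribosomal protein genes were lower in replicate 1 (-0.11) and higher in replicate 3 (0.09), and translation factors followed with -0.06 and 0.10. Glycolysis genes were higher in replicate 3 (0.12), and immediate early and stress genes lower in replicate 2 (-0.25) and higher in replicate 3 (0.32). With plain library totals the median shift of all genes in replicate 3 was 0.16, against 0.02 with TMM. With means for medians, the replicate 3 shifts of the ribosomal, glycolysis and immediate early lists fell inside the range, and with unmatched random lists so did both translation shifts, the ribosomal and glycolysis shifts of replicate 3 and the mitochondrial shift of replicate 1. Without replicate 2 the glycolysis and immediate early shifts of replicate 3 fell inside the range (0.08 and 0.23) and the mitochondrial shift of replicate 1 became 0.06; without replicate 3 the translation shift of replicate 1 (-0.03) and the immediate early shift of replicate 2 (-0.10) did, and without replicate 1 the ribosomal shift of replicate 3 (0.04).

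**Figure D3:**
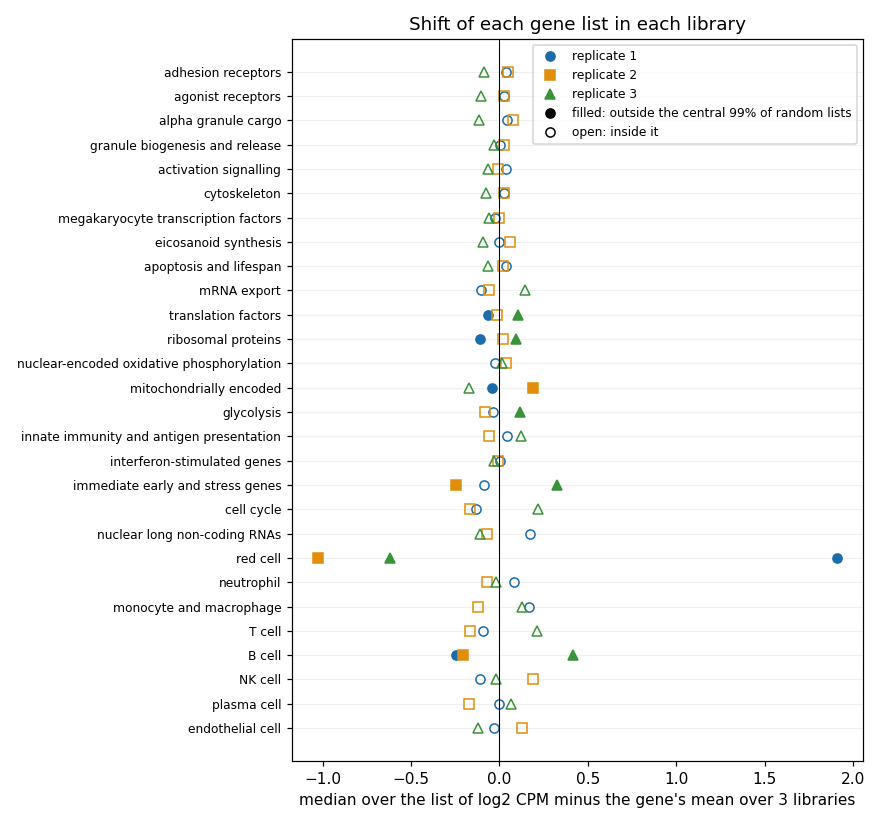
Median log2 shift of each gene list in each of the 3 libraries, relative to each gene's mean over the libraries; filled points lie outside the central 99% of random lists matched on expression. The red cell list in replicate 1, at 1.91, and the B cell list in replicate 3, at 0.42, lie farthest above 0.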

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

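Settings added after seeing the data were the RefSeq background, list medians, totals without mitochondrial genes, the shares without globins or Lyz2, list shifts without a replicate, and the CPM of named genes under other settings. The share of the 10 highest genes, the count of pairs above 0 and all 516 recomputed CPM values of named genes stayed within their spread or 1.5 times. Leaving out 1 of 3 libraries always moves a mean by less than its SD. Means and shares without a replicate could therefore not leave their spread, and are no check of stability. Hba-a1 counted as unchanged, although it was at 20678, 2768 and 3424 CPM in replicates 1, 2 and 3. Detected genes numbered 4000 at 5 CPM. The number of lists called was 0 at 0.5 CPM (1 at an unadjusted p under 0.05), 4 to 6 without a replicate and 20 with the RefSeq background; there, 70.8% of interferon-stimulated and 10% of organ-restricted genes were detected and both directions reversed, since genes outside the tables count as not detected. Totals without the 10 highest genes raised the platelet share to 20.8% and the leukocyte share to 0.332%. Dividing by gene length gave 12.9% for platelet lists, 4.74% for red cell genes and 0.233% for leukocytes. By plain counts, leukocyte lists without Lyz2 took 0.0497%. Variable genes numbered 11 with plain totals, 43 with a robust prior, 49 by DESeq2, 11 without red cell and leukocyte genes (11 of the 22 were removed) and 2 to 29 without a replicate. Lists shifted numbered 3 to 7 without a replicate.

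Signs reversed in some shifts without a replicate: those ranged from -0.018 to 0.0035 for signalling in replicate 2, -1.27 to 0.14 for red cells in replicate 3, -0.11 to 0.061 for mitochondrial genes in replicate 1 and -0.30 to 0.042 for B cells in replicate 2. With 2 libraries left, each gene's shifts are equal and opposite. The Pf4 to Ppbp ratio was 0.85 by length and -0.056 to 0.0058 without a replicate, and Vamp8 to Vamp3 0.078 by length. For other moved values the cause was not tested. Of the other 500 recomputed shifts, 474 stayed on their side of the range, 12 moved out of it and 14 into it; other library scalings move a list and its random lists alike and are a weak check. A background of genes with at least 1 count was not run, since it removes no gene. No paired analysis was possible because there is 1 group. At this depth a 2-fold difference in 1 library was found in 1 of 50 genes simulated with dispersions on the trend. Small differences between libraries were thus mostly not detectable.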

Other observations

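The lists fixed for platelets missed much of the most abundant RNA. Of the 20 highest genes, 9 were in no list, and the 10 highest genes outside all lists held 19.5% ± 0.519 of counts (SD, n = 3). They were Ctla2a, Fth1, Nrgn, Tsc22d1, Gng11, 1810058I24Rik, Ctla2b, Parvb, Atp2a3 and Marchf2, a membrane-bound ubiquitin ligase gene at 4454 ± 179 CPM. Several genes chosen as marks of other tissues were steady and not rare: Aqp1 at 364 ± 24.6 CPM, Mbp at 295 ± 9.03 CPM and Lyz2 at 1387 ± 117 CPM, while the other genes of their lists were mostly low. Tmsb4x, an actin-binding peptide gene, was at 4.76 ± 0.149 CPM and its relative Tmsb10 at 34.9 ± 3.05 CPM; both were picked after their values were seen, and the level of Tmsb4x is uncertain because the treatment of reads that map to several places is not given in the sources used here.

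In the weighing of patterns that follows, the tests of globin reads, of a lower platelet share and of copies of ribosomal protein genes were chosen only after the result was seen. So was the comparison made for scaling. The further lists of red cell and B cell genes were fixed after the shifts of the first lists but before their own values were seen. No biological explanation was tested, since the 3 libraries form 1 group and the animal and the batch cannot be told apart.

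Red cell genes were higher in replicate 1, by a median log2 shift of 1.91. Shared globin reads were argued against as the whole cause, since 17 of the 21 genes called with replicate 1 highest were not globin genes. The shift was not shared by genes of the same level, since the central range of random matched lists ended at 0.10. That range had also picked the list out, so it gives no separate test of scaling. Red cells or reticulocytes in the preparation may be the source: 17 further red cell genes had a median shift of 0.16, above all random lists (central range -0.09 to 0.11), with 16 of them above their means. That shift was far smaller than that of the first list, and the most abundant of these genes, Epb41, Isg20 and Blvrb, exceeded the mean of the others in replicate 1 by only 1.17, 1.19 and 1.01 times (TMM-scaled CPM). The labels call the platelets purified and name no step that removes red cells. In all 3 libraries 15 of 19 genes of the first list were detected, 78.9% against 77.7% of other genes. That share is no sign of red cells by itself. Red cells left in each library or platelets themselves could give the counts of these genes, and these data cannot tell them apart. Whether the rise in replicate 1 came from cells or from the animal stays open.

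B cell genes were higher in replicate 3, by a median log2 shift of 0.42, against an upper end of 0.19 for random matched lists. The same comparison had picked the list out, so it gives no separate test of scaling. An equal rise of all other cell types, through a lower share of platelet RNA, was argued against as the whole cause by 34 genes of the other leukocyte lists. Their median shift of 0.17 lay below that of the B cell list by 0.25 (bootstrap 95% interval 0.14 to 0.43), though the B cell list had been picked for its shift. The pool was mixed. Its T cell genes had a median shift of 0.21, with 12 of 12 above their means. Their list took 0.00438%, 0.00429% and 0.00659% of counts in replicates 1, 2 and 3, against 0.0308%, 0.0305% and 0.0505% for the B cell list. The rise was thus not particular to B cell genes. The 34 genes were also higher in replicate 3 at the median, so a lower platelet share as part of the cause was not excluded. By plain counts, though, the platelet lists took 13.5%, 13.8% and 14.2% in replicates 1, 2 and 3, so their share was not lower in replicate 3. Genes at 100 CPM or more had a median shift there of -0.12 with TMM scaling and 0.02 with plain totals. The answer thus depends on the scaling. B cells in the preparation may be the source: 25 further B cell genes had a median shift of 0.49 in replicate 3, above all random lists, with 24 above their means. The most abundant genes of the first list were Cd74 at 113, 101 and 167 CPM and H2-Aa at 77.3, 82.2 and 127 CPM in replicates 1, 2 and 3. Of the further list, Ralgps2 was highest at 128, 115 and 129 CPM, with a shift of -0.08 in replicate 3, and Cd37 next at 33.8, 35.3 and 44.9 CPM, with 0.11.

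Ribosomal protein genes, whose products are made in about equal numbers, ranged 539-fold in CPM. Reads shared with near-identical copies may be part of the cause: across 70 genes, which are not independent replicates, RPKM was higher where more 50-base stretches of the transcript were found in no other gene (Spearman's rho 0.34, permutation p = 0.00424; Pearson's r 0.36). The 35 genes with at least 50% such stretches had a median of 17.7 CPM and the other 35 one of 6.87 CPM. The genes that set the 539-fold range went the other way. Rpl41, the highest at 367 CPM, had 46.9% such stretches, and Rps29, the lowest at 0.681 CPM, had 64.2%. The transcript used per gene was the protein-coding one nearest the table's gene length, chosen after a first table of longest transcripts was seen. For some genes it was still much longer than that length. Rps20 (RPKM 89.3, 92.6% such stretches) was scored on 3706 bases against 502, and Rpl35 (RPKM 7.44, 59.9%) on 946 against 452. The effect of such cases on rho was not tested. Short transcripts were not decided: RPKM against gene length gave a rho of -0.071 (permutation p = 0.558; Pearson's r -0.12). A rho of 0 or below had been set to count against that explanation, and the need for p under 0.05 was added after the value was seen, because a rho this close to 0 lies within its spread.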
